A study of Caenorhabditis elegans with 2 samples.

How the data were processed

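Chromatin from whole young adults of strain OP572 (64 h, 2 biological replicates numbered 4 and 5) was fragmented by sonication and precipitated with an antibody to GFP, per the labels' protocols. The sources used here give 1 group only, so no comparison between conditions was made. Per the labels, positions are in build ce11. Per the listings deposited beside the samples, candidate regions were called on the alignment of each replicate alone and on the pooled alignments of both, each with a control alignment, and the list passing IDR was derived from those candidates. The peak caller, its version and the IDR threshold are not given in the sources used here. The 2 listings hold no measurements and were read only for how the region lists were derived.

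The height of each region is the signal value that the authors deposited with each summit, a number from peak calling whose scale is not stated. It was used to rank and filter regions within a list and was never compared in size between lists; the signals of the replicates were compared only by correlation. The authors also deposited the −log10 of a q value for each summit. This value had a ceiling in every list (2.89 for 1949 pooled summits, 2.80 for 319 of replicate 4 and 3.63 for 2110 of replicate 5), and all 1030 summits that passed IDR stood at the ceiling, so it ranked nothing there and was not used further. The 1030 summits that passed IDR were the 1030 highest by signal of the pooled list: the lowest of them had a signal of 110.4, and the next pooled candidate was below it. Every candidate list stopped at 30000 summits, so the number of candidates carries no information on depth. Library sizes were not used here, and the precision of each region is unknown. Intervals given for shares are exact (Clopper-Pearson, 95%) and cover the counting of regions only.

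Summits that shared an interval were merged to the one with the highest signal, which turned 1030 summits into 988 regions, 976 of them nuclear. The 20 mitochondrial summits were left out of tests of location. The reference for location, non-coding genes and motifs was the 28554 nuclear pooled candidate regions that overlapped no region passing IDR. Genes came from Ensembl release 115 for WBcel235, whose coordinates are those of ce11, and sequence from the RefSeq assembly of the same build; chromosome lengths and names were compared before use. Each summit was given 1 class in the order promoter window (1000 bp upstream to 200 bp downstream of the start of a protein-coding gene), 5' UTR, 3' UTR, coding exon, non-coding RNA gene, intron, intergenic. Arms were the outer 30% on each side of an autosome and ends the outer 100 kb.

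Shares were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family: 7 location classes, 8 non-coding classes, 26 gene and tissue lists, and 12 motifs, with a threshold of 0.05. Gene lists were tested against the 6175 protein-coding genes with a pooled candidate summit in the promoter window, since only these could have been bound; 598 were bound, and 251 of those shared their highest summit with another bound gene. The lists and motifs, the tests and the promoter window were set before the data were examined. Motifs were sought on either strand within 50 bp of the summit and compared with candidates drawn 3 to 1 after matching on GC content in bins of 5% and on promoter location. Overlap of the replicates was tested with 1000 circular shifts along each chromosome (one-sided), and correlations across regions with 100000 permutations (two-sided).

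The genes and regions named were fixed by a rule set in advance: gei-17 and unc-119, the 25 highest summits that passed IDR, up to 4 bound members of each list with the highest signal, and the highest region of each chromosome. Each region was named by the gene whose promoter window held the summit, or else by the nearest start. Other genes and regions were chosen after their values were seen, among them pks-1, lin-52, Y17G9B.5, Y55F3AR.2 and Y22D7AL.10 as neighbours of bound genes, rpl-12, mef-2, the snRNA genes beyond sls-2.1 and sls-2.4, and every gene of the closing observations. The boundary of the 50 highest regions, all comparisons of X with autosomal regions within the list that passed IDR, the search for 8 bp words, 1 added motif and 1 added gene list (dosage compensation and sex determination, 1 of 7 bound, sdc-2) were also chosen after the data were seen.

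Alternatives were the list of either replicate alone in place of the IDR list, a stricter and a looser region threshold, other promoter windows, other references (all protein-coding genes, nearest genes, circular shifts, chromosome lengths), other overlap criteria, other numbers of top regions, other motif windows and flanking controls. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated lists of 976 regions drawn from the candidates. With no planted difference, the X share and the promoter share were each called in 5% of 100 draws, and a planted odds ratio of 1.5 was called in 100% of draws with a median estimate of 1.52 and 1.51. The list of cytosolic ribosomal proteins, with 64 genes with a candidate, was the only gene list planted. At an odds ratio of 4 it was called in 96% of draws of 598 bound genes, and without planting in 0%, while some other list was called in 4%. The rate of 96% does not cover lists with fewer genes. For gene lists, single genes were drawn and not summits. In the data, 251 of the 598 bound genes shared their highest summit with another bound gene. The draws did not take shared summits into account, so these rates do not cover their effect on the gene list tests.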

Results

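GEI-17 is a SUMO E3 ligase of the PIAS family in the nematode Caenorhabditis elegans. Its association with chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adults aged 64 h, males and females together per the labels. The worms were of strain OP572, which carries an integrated transgene for GEI-17 fused to GFP and FLAG tags beside a rescuing copy of unc-119, and chromatin was precipitated with an antibody to GFP. There was 1 group of 2 biological replicates, numbered 4 and 5. The data were 4 lists of regions in build ce11 coordinates. There were 30000 candidate summits for each replicate and 30000 for the pooled replicates. Of the pooled summits, 1030 passed the irreproducible discovery rate (IDR) filter. The pooled candidates are labelled as peaks and background together, so the reference drawn from them includes background. After summits that shared an interval were merged, 976 nuclear regions passed IDR, and 28554 other nuclear candidates served as the reference. No read counts were used, so the depth behind each region is unknown. Worms without the tag and other tagged proteins were not analysed. Signal that does not depend on GEI-17 therefore cannot be told apart at any region, gene list or gene class below. With 1 group no conditions could be compared, and every p-value below describes these lists of regions and not a population of worms.

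The strongest nuclear GEI-17 regions lay on the X chromosome. Among the 25 highest summits of the list that passed IDR, 15 were mitochondrial and the other 10 were all on X. The highest nuclear region, X:11092966–11095162, was intergenic, with its summit 3994 bp downstream of the start of the nearest protein-coding gene, W02H3.3, and had a signal of 3469 in the pooled list, 1783 in replicate 4 and 1743 in replicate 5. The next was X:9465209–9466798, intergenic near ZK899.6, at 3139.9. The region at X:8035557–8037191 had a signal of 3090.2 and its summit lay in intergenic sequence upstream of xol-1 (at −4867 bp from the annotated start), the switch gene of worm sex determination and dosage compensation. Further X regions lay in an intron of mom-1, which encodes a Wnt secretion factor (X:6295766–6297317, signal 3058), in the promoter window of nspc-17 (X:14525103–14527073, 2794) and in intergenic sequence near F55G7.5 (X:11936638–11938309, 2643). Those near F22H10.2, K02D3.1, F20B6.9 and fbxb-58 had signals of 2509, 2458, 2445 and 2431, all in intergenic sequence.

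X regions also took a larger share of the whole list than of the candidates. Of the 976 regions that passed IDR, 310 (31.8%, 95% exact interval 28.8–34.8) were on X, against 22.4% of the 28554 other candidates, an odds ratio of 1.62 (1.40–1.86, two-sided Fisher's exact test, p = 3.23e-11). X held 17.5 regions per Mb, and the autosomes between 6.02 (V) and 10.1 (III). The excess was steepest at the top. X held 23 of the 25 highest nuclear regions (92%, 95% exact interval 74.0–99.0) in the pooled list, and also 23 of 25 in the list of each replicate. Of the 50 highest, a boundary chosen after the ranks had been seen, 32 were on X (64%, 49.2–77.1), an odds ratio of 6.17 over the other candidates (3.36–11.7, two-sided Fisher's exact test, p = 3.63e-10). These 32 regions had a median width of 1171.5 bp and a median signal of 1789, against 369.5 bp and 540.2 for the 18 autosomal ones. The contrast in width came from ranks 1 to 25, where the 23 X regions had a median width of 1542 bp; at ranks 26 to 50 X held 9 of 25 regions (36%), with a median of 367 bp against 355.5 bp for the autosomal ones. Of the 32, 22 were intergenic, 5 had their summit in a promoter window, 4 were intronic and 1, inside pks-1, lay in a coding exon. All 32 had an overlapping candidate in both replicates, as did 969 of all 976 regions.

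**Figure D1:**
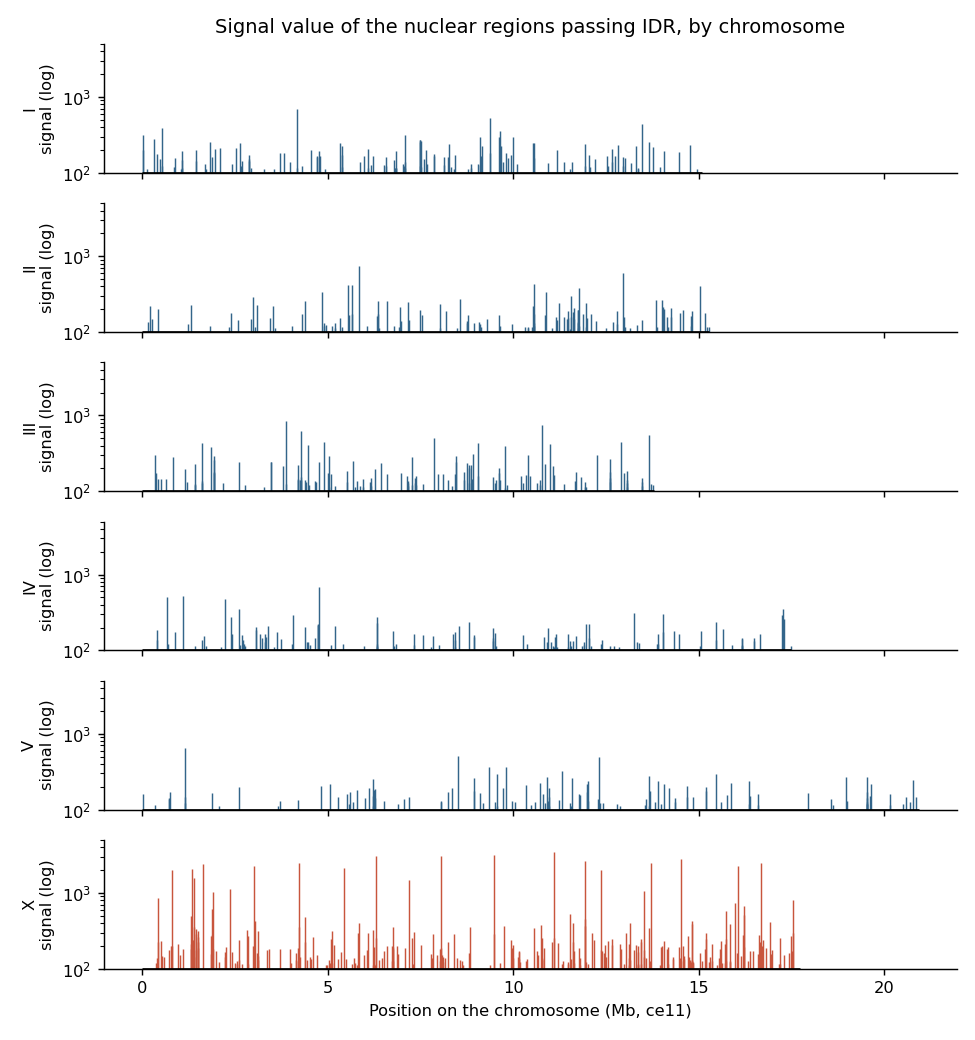
Signal value (log axis, as deposited for the pooled replicates) of the 976 nuclear regions that passed IDR against position in Mb (ce11), 1 panel per chromosome, with a vertical line for each region, X in red and autosomes in blue. The highest X region reaches 3469 and the highest autosomal one, upstream of rpl-3 on chromosome III, reaches 835.

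**Figure D2:**
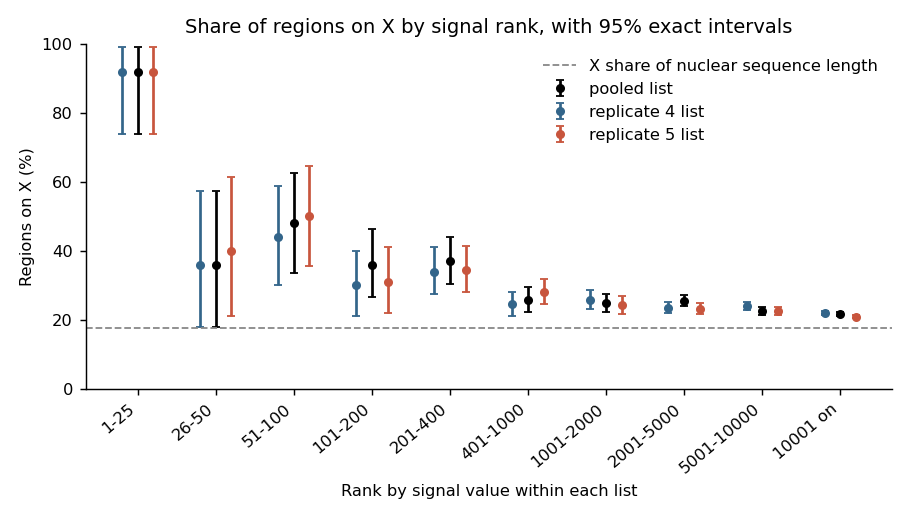
Percent of nuclear regions on X by rank of signal within the pooled list and the list of each replicate, with 95% exact intervals; the dashed line is the X share of nuclear sequence length, 17.7%. The share is 92% at ranks 1 to 25 in all 3 lists and 21.8% beyond rank 10000 of the pooled list.

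The highest autosomal region, on chromosome III, was 278 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit, with a signal of 835 (III:3867348–3867773; 411 in replicate 4 and 428 in replicate 5). The highest on IV lay between Y17G9B.5 and rpl-20 (IV:4749908–4750229, signal 684). On II and I the highest regions lay in the promoter windows of ZK1248.17 (II:5844630–5845263, 751) and egg-5 (I:4171977–4172679, 704), within 200 bp of sls-2.1 and sls-2.4, genes for SL2 spliced leader RNA. The highest on V had a signal of 644 and its summit lay in a non-coding RNA gene, with cmd-1, which encodes calmodulin, as the nearest protein-coding gene (V:1151259–1151711).

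GEI-17 regions concentrated upstream of protein-coding genes and were scarce within them. The summit lay in a promoter window, from 1000 bp upstream to 200 bp downstream of an annotated start, for 482 of 976 regions (49.4%, 95% exact interval 46.2–52.6), against 22.97% of other candidates (odds ratio 3.27, 2.87–3.73, two-sided Fisher's exact test, p = 1.98e-69). Coding exons held 3.79% of the regions against 25.8%, introns 13.9% against 27.5%, and 3' UTRs 0.820% against 3.76%. Intergenic sequence held 23.1% against 16.4%, and genes for non-coding RNA 7.79% against 2.27%. All 6 of these classes passed the two-sided Fisher's exact test after Benjamini-Hochberg adjustment over 7 classes, with adjusted p from 3.92e-74 for coding exons to 1.69e-07 for intergenic sequence, and 5' UTRs did not (1.23% against 1.28%, adjusted p = 1). The 3' UTR call was lost when replicate 4 alone was ranked in place of the IDR list (odds ratio 0.662, adjusted p = 0.0589 by Fisher's exact test). On the autosomes alone the intergenic share did not pass (18.0% against 15.2%, odds ratio 1.22, two-sided Fisher's exact test, adjusted p = 0.0650), while on X alone it did (33.9% against 20.6%, odds ratio 1.98, adjusted p = 1.91e-07).

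Promoter windows held a smaller share of the regions on X than of those on the autosomes, namely 127 of 310 X regions (41.0%) and 355 of 666 autosomal ones (53.3%), an odds ratio of 0.608 (0.458–0.806, two-sided Fisher's exact test chosen after the X regions had been seen, p = 0.000349). Both shares were above those of candidates on the same chromosomes, with odds ratios of 2.82 on X and 3.63 on the autosomes, and the candidates also had a lower share on X (19.8% against 23.9%). Promoter regions were themselves more often on X than promoter candidates were, at 127 of 482 (26.3%) against 19.3% (two-sided Fisher's exact test, p = 0.000286).

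Genes for ribosomal proteins were bound more often than other genes. A gene was counted as bound when a summit that passed IDR lay in its promoter window, and the reference was the 6175 protein-coding genes with any candidate there, of which 598 (9.68%) were bound. Of 64 such genes for cytosolic ribosomal proteins, 20 were bound (31.3%, 95% exact interval 20.2–44.1), an odds ratio of 4.35 (2.41–7.60, two-sided Fisher's exact test, adjusted p = 3.28e-05 over 26 lists). The highest were rpl-3 (835), rpl-20 (684), rpl-35 (502) and rpl-15 (499). All 20 summits lay upstream of the annotated start, at a median of −287 bp. The regions of all 20 overlapped a candidate in both replicates, as did 969 of all 976 regions that passed IDR. Of the 20 genes, 14 shared their summit with another bound gene, so the count can include neighbours: the summit of rpl-20 also lay in the window of Y17G9B.5.

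Translation factors and chaperones were the other lists that passed the test. Of 28 translation factor genes, 8 were bound (28.6%, odds ratio 3.77, 1.43–8.97, two-sided Fisher's exact test, adjusted p = 0.0344), led by eif-3.C (301), eef-1A.2 (287), eef-2 (227) and eef-1G (195). Of 43 chaperone genes, 11 were bound (25.6%, odds ratio 3.25, 1.47–6.65, two-sided Fisher's exact test, adjusted p = 0.0268). They included cct-8, a subunit of the cytosolic chaperonin (523), hsp-60, the mitochondrial chaperonin (435), hsp-1, a cytosolic Hsp70 (349), and dnj-9 (335). Of the bound genes, 4 of the 8 translation factors and 8 of the 11 chaperones shared their summit with another bound gene: those of cct-8 and hsp-60 also lay in the windows of Y55F3AR.2 and Y22D7AL.10. The translation factor call ended when replicate 5 was used without replicate 4 (odds ratio 3.18, adjusted p = 0.119), with the looser region threshold (2.67, adjusted p = 0.0866) and on autosomes alone (3.69, adjusted p = 0.0632), all by two-sided Fisher's exact test. The chaperone call ended with the wider promoter window (odds ratio 2.57, adjusted p = 0.0608 by two-sided Fisher's exact test) and on autosomes alone (3.12, adjusted p = 0.0632).

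Among the chromatin regulators of the synMuv and related groups, 5 of 16 were bound (31.3%, odds ratio 4.26, 1.16–13.4), which did not pass adjustment (two-sided Fisher's exact test, adjusted p = 0.0962). These were lin-54 (309), lin-9 (307), lin-53 (301), lin-15B (126) and lin-52; lin-9, lin-52, lin-53 and lin-54 encode members of the DRM complex. The lin-54 summit also lay in the window of rpl-12. Respiratory chain and ATP synthase genes were bound at 6 of 24 (25%, adjusted p = 0.124 by two-sided Fisher's exact test), with cox-5A at 450.03, atp-1 at 204 and cox-5B at 182. The chromatin list passed with the looser threshold and with the wider window (adjusted p = 0.0178 and 0.0275 by two-sided Fisher's exact test), and the respiratory list with the stricter threshold and the wider window (0.0403 and 0.0386).

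No gene of the SUMO pathway itself was bound, at 0 of 7 with a candidate, and none of 7 reported SUMO targets and partners; a count of 0 of 7 allows a share of up to 41.0%. Genes for C-type lectins, lysozymes and saposin-like proteins were bound at 1 of 56 (clec-126, 222) and chemoreceptors at 5 of 109 (sre-23, 237; sri-5, 203), below the reference but not past adjustment (adjusted p = 0.172 and 0.267 by two-sided Fisher's exact test). Both lists passed as less often bound in other settings of the same exact test: the lectin list with the looser threshold (odds ratio 0.0859, adjusted p = 0.00634) and the nearest gene (0.306, 0.0428), and chemoreceptors with the looser threshold (0.373, 0.0235), the wider window (0.342, 0.01) and the nearest gene (0.160, 1.42e-13). The nearest-gene setting took all nuclear protein-coding genes as reference, with 287 genes of the lectin list and 1299 chemoreceptors. Genes with no candidate in their window entered it, so its values do not describe genes with a candidate alone. The remaining lists also did not pass: DNA damage response and repair had 2 of 13 (pcn-1, which encodes PCNA, 295, and brc-1, the BRCA1 homologue, 123), RNA polymerase II, TFIID and Mediator 5 of 29 (mdt-19, 241, and rpb-11, 202), and splicing and RNA processing 5 of 30 (snr-4, 220.0). Histones had 1 of 20 (his-37, 295), collagens 2 of 41 (col-185, 176), proteasome subunits 2 of 18 (rpn-3, 240.2), xenobiotic metabolism 2 of 42 (gst-27, 177), nuclear hormone receptors 6 of 93 (nhr-68, 259), homeobox genes 1 of 19 (ceh-38, 216) and the Argonaute and small RNA pathway 1 of 10 (ego-1, 200.3).

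Of 49 tissue marker genes with a candidate, 2 were bound, and the 49 were not tested as 1 set: act-4 of the body wall muscle list (1 of 6, signal 112) and spe-48 of the sperm list (1 of 14, signal 209), whose region had no overlapping candidate in replicate 5. The lists for pharynx, intestine, hypodermis, neurons, and germline and oocyte had 0 of 3, 0 of 9, 0 of 3, 0 of 5 and 0 of 9. None of the 7 tissue lists passed the two-sided Fisher's exact test, either adjusted or at an unadjusted p under 0.05, and the lists held between 3 and 14 genes with a candidate.

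**Figure D3:**
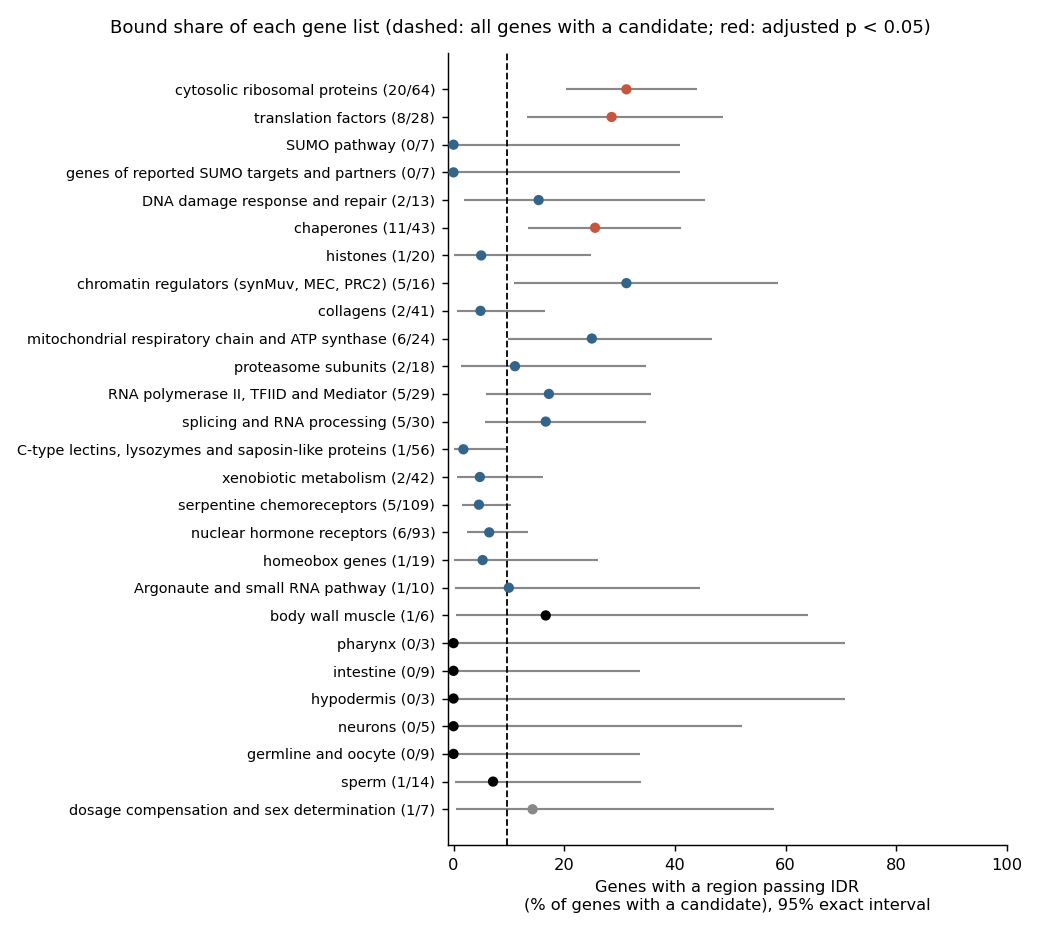
Percent of genes with a candidate that had a region passing IDR in the promoter window, by gene list, with 95% exact intervals and the counts beside each name; red marks adjusted p under 0.05, blue other gene lists, black tissue markers, grey 1 list added after the data were seen. Ribosomal proteins stand at 31.3%, against 9.68% of all genes with a candidate (dashed line).

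Short non-coding genes lay near many GEI-17 regions. A tRNA gene was within 200 bp of the summit of 96 regions (9.84% against 1.04% of other candidates, odds ratio 10.4, 8.10–13.3), a snoRNA gene of 50 (5.12% against 0.417%, 12.9, 9.02–18.2), and an snRNA gene of 19 (1.95% against 0.133%, 14.9, 8.08–26.6). Genes of the broad ncRNA class were near 226 regions (23.2% against 6.30%, odds ratio 4.48, 3.81–5.24). These 4 classes passed the two-sided Fisher's exact test after adjustment over 8 classes, with adjusted p of 9.37e-55, 4.28e-33, 2.40e-14 and 4.76e-61 in the order named. Counted by gene, 110 of 612 tRNA genes, 51 of 346 snoRNA genes and 17 of 129 snRNA genes had a region nearby. Some of these regions also made a protein-coding gene count as bound. Examples, chosen after their values were seen, were sre-23 and rps-26, whose regions lay near snoRNA genes, and snr-4, near an snRNA gene. Position alone cannot tell to which gene such a region belongs. The highest snRNA genes were sls-2.1 (751), sls-2.4 (704), sup-6 (595) and sls-2.2 (422), examples chosen after their values were seen. MicroRNA genes did not pass (5 regions, odds ratio 2.33, two-sided Fisher's exact test, adjusted p = 0.0989), although they did with either replicate alone (adjusted p = 0.0249 without replicate 4 and 0.0101 without replicate 5). They also passed the two-sided Fisher's exact test with the stricter threshold (adjusted p = 0.0374) and on the autosomes, which held all 5 regions (odds ratio 3.89, adjusted p = 0.0203). In the main setting, genes for piRNA, pseudogenes and rRNA did not pass either. Pseudogenes passed as less frequent without replicate 5 (odds ratio 0.463, adjusted p = 0.0101) and with the looser threshold (0.407, adjusted p = 6.63e-05), by two-sided Fisher's exact test.

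**Figure D4:**
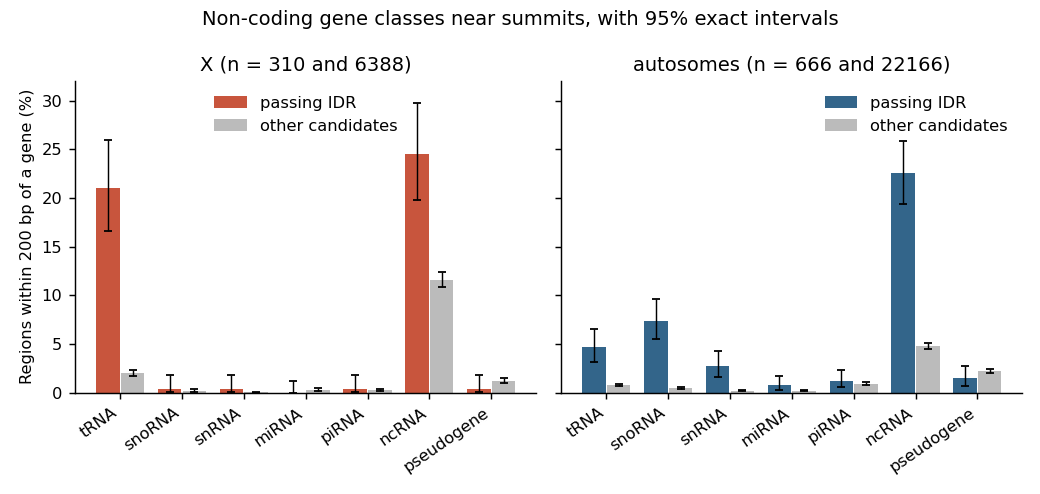
Percent of regions with a gene of each non-coding class within 200 bp of the summit, for X and for the autosomes, regions passing IDR in colour and other candidates in grey, with 95% exact intervals. tRNA genes are near 20.97% of X regions and 4.65% of autosomal ones, snoRNA genes near 0.323% and 7.36%.

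Of 12 sequence motifs fixed in advance, 2 were more frequent within 50 bp of the summits than in candidates matched for GC content and promoter location. The GAGA repeat GAGAGAGA was present at 65 regions (6.66% against 2.33%, odds ratio 2.99, 2.08–4.30, two-sided Fisher's exact test, adjusted p = 2.81e-08). The heat shock element TTCTAGAA was present at 13 (1.33% against 0.240%, odds ratio 5.61, 2.07–16.7, two-sided Fisher's exact test, adjusted p = 0.00109), a call that ended among the regions of higher signal kept by the stricter threshold (odds ratio 4.54, adjusted p = 0.117). The other 10, among them the E-box (4.71% against 3.36%), the E2F site (1.13% against 0.514%) and the telomere repeat (0.102% against 0.617%), did not pass, with adjusted p of 0.157 or above by the same test. The E-box passed without replicate 4 (adjusted p = 0.00605 by two-sided Fisher's exact test) and without replicate 5 (0.00431). It also passed the two-sided Fisher's exact test within 100 bp of the summit (adjusted p = 0.02) and against flanking sequence (adjusted p = 5.44e-05), which was not matched for GC content.

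The replicates named largely overlapping regions. Of the 1006 nuclear regions at the top of the replicate 4 list, 631 (62.7%, 95% exact interval 59.7–65.7) overlapped one of the 974 at the top of the replicate 5 list, against a mean of 0.958% and a maximum of 2.19% in 1000 circular shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The share was 75.2% on X and 57.4% on the autosomes. Over 5 alternatives with other overlap criteria or numbers of top regions, the share for all nuclear regions ranged from 48.9% to 69.2%. Of the 976 regions that passed IDR, 969 had a candidate in both replicates, and across these regions the signals of the replicates correlated with Pearson's r of 0.776 on the log2 scale and Spearman's rho of 0.571 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Taken apart, X regions had r of 0.896 and rho of 0.730, and autosomal ones r of 0.575 and rho of 0.479. Regions are not independent replicates, and these correlations describe regions that stood highest by pooled signal, to which both replicates contributed. Passing IDR did not by itself mean that a region was found in both replicates.

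**Figure D5:**
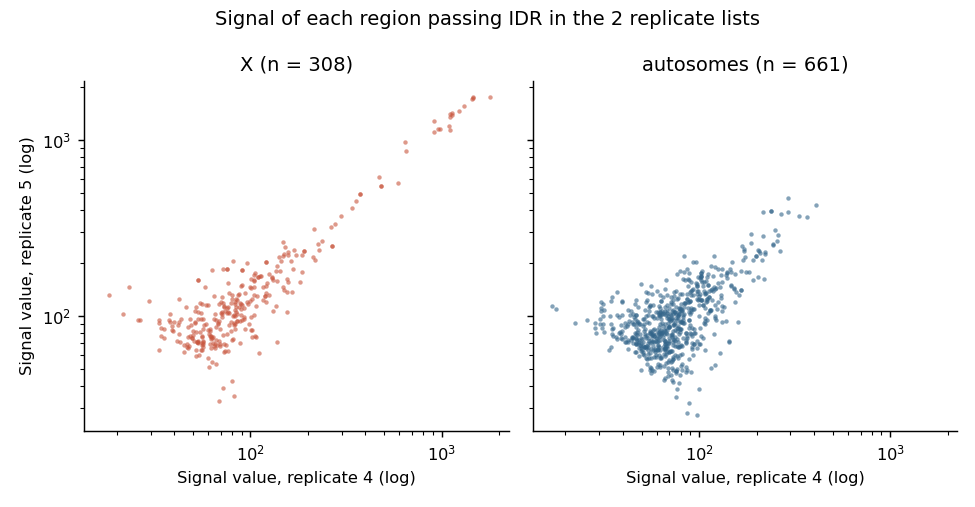
Signal value of each region passing IDR in replicate 4 and in replicate 5 (log axes), 1 point per region, X (308 regions) in red and autosomes (661) in blue. The X region highest by pooled signal stands at 1783 in replicate 4 and 1743 in replicate 5, and the region upstream of rpl-3 on chromosome III at 411 and 428.

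On the autosomes, GEI-17 regions lay in the arms less often than other candidates, a difference that did not pass against chance placement along the same chromosomes. The outer 30% of each autosome on either side held 359 of 666 regions (53.9% against 63.5%, odds ratio 0.672, 0.574–0.787, two-sided Fisher's exact test, p = 6.08e-07). Against 1000 circular shifts of the same regions the odds ratio was 0.781 and did not pass (two-sided permutation p = 0.064). Chromosome ends, where GEI-17 has been linked to telomere anchoring, held 9 regions within 100 kb (0.922% against 1.46%, odds ratio 0.628, 0.284–1.21, two-sided Fisher's exact test, p = 0.217), and of the 6 alternatives 1 passed, the ranking of replicate 4 alone (odds ratio 0.410, p = 0.0203 by the same exact test).

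Across all 976 regions, no rank relation between signal and distance to the nearest protein-coding start passed the test (Spearman's rho 0.0491, two-sided permutation p = 0.127; Pearson's r 0.103, p = 0.0015). When X and the autosomes were taken apart, rho was 0.153 across the 310 X regions (two-sided permutation p = 0.00733) and −0.0343 across the 666 autosomal ones (p = 0.377), and the difference between them was not tested. With the signal of replicate 5 alone, without replicate 4, rho over all regions was 0.0882 and passed (two-sided permutation p = 0.00615). These are relations across regions of one list.

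The counts of pooled candidates around the genes carried on the transgene depended on the distance taken. Within 20 kb of gei-17 (I:9100843–9108140) lay 2 summits that passed IDR, against a median of 0 over all protein-coding genes (90.9 percentile). The higher was at I:9095598–9096041 with a signal of 293. Its summit was 12320 bp downstream of the annotated start of gei-17, and thus beyond its end, and lay in the promoter window of mef-2 (at −137 bp from the start). The locus had 12 pooled candidates, equal to the median of 12 over all protein-coding genes, and its highest signal stood at the 95.4 percentile. Within 10 kb it had 7 candidates against a median of 6, and within 40 kb 37 against a median of 23 (84.0 percentile). Within 20 kb of unc-119 (III:10902641–10908935) no summit passed IDR and there was 1 pooled candidate (5.55 percentile).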

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

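Both tests in this part were chosen only after the mitochondrial regions had been seen.

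The list that passed IDR held 20 summits on the mitochondrial genome, which took no part in the comparisons, and the list of replicate 5 held 23. A count of 0 would allow up to 3. The highest, at mitochondrial position 4709, had a signal of 13745 in the pooled list, above the 3469 of the strongest nuclear region. Others lay near COX3 (8569) and ND1 (5687), genes for subunits of the respiratory chain.

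The mitochondrial regions are weighed here as to whether they mark sites. Against a property shared by both replicates, the list of replicate 4 held 0 mitochondrial summits. The regions of replicate 5 covered 87.1% of the mitochondrial genome, which met the share asked of reads spread along the whole molecule. Those that passed IDR covered 75.5%, which fell short of that share. Uneven recovery or filtering of mitochondrial DNA between the libraries is a candidate explanation. Reads were not used here, so a filter on mitochondrial sequence in 1 of the pipelines or a real difference between the worms remains open, and no biological explanation was tested.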

How the results depend on the processing

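The alternatives chosen after the data were seen were the matched reference, the promoter-only and other-only subsets and the count of every summit for the X share; the split of the promoter share by chromosome; autosomes alone and an added list for gene lists; an added motif; and every alternative for the 50 highest regions. Over 489 comparisons of a result with an alternative, 437 kept their direction and side of the threshold, 8 fell below it, 30 rose past it, 13 counts or values moved and 1 reversed. Results that passed under neither setting were counted as kept even where their direction turned. The added gene list and the added motif left the other odds ratios as they were and changed only the adjustment. The promoter share was also counted a further time among the location classes. The number kept is therefore not a measure of robustness. The odds ratio of the promoter share ranged from 2.48 to 3.76 over 9 alternatives and that of the X share from 1.39 to 2.17, and each passed its test in all 9. The X share of the 50 highest regions ranged from 64% to 72%.

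The lower arm share did not pass against circular shifts (odds ratio 0.781, two-sided permutation p = 0.064). The odds ratio of the end share ranged from 0.410 to 0.685 when 1 replicate was left out, and passed without replicate 5 only. The relation of signal and distance ranged from 0.0286 to 0.0882 with 1 replicate left out, and passed without replicate 4 only. The cause of these was not tested.

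The number of gene lists that passed was 3, all more often bound, and became 5 with the looser threshold (2 of them less often bound), 5 with the wider window (1 less often), 9 with all protein-coding genes as reference (2 less often), 5 with the nearest gene (2 less often) and 1 on autosomes alone, where ribosomal proteins remained with an adjusted p of 3.51e-05 by Fisher's exact test; the ribosomal list passed under all 10 alternatives. With all genes as reference, genes that had no candidate, and so could not be bound, enter the comparison, which raises the count by construction. The nearest-gene setting also took all protein-coding genes as reference, so genes with no candidate in their window enter there too. The number of motifs that passed was 2, and became 1 with the stricter threshold, 4 within 100 bp of the summit (1 less frequent) and 7 against flanking sequence (2 less frequent). Flanks were not matched for GC content, and against them the T-block TTTTTTTT turned from 1.04 to an odds ratio of 0.310 (Fisher's exact test, adjusted p = 1.2e-12). The causes of the other changes were not tested. Around gei-17, 2, 2 and 4 summits passed IDR within 10, 20 and 40 kb, with 7, 12 and 37 pooled candidates against medians of 6, 12 and 23; around unc-119 none passed, with 0, 1 and 12 candidates.

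The overlap and the correlation of the replicates need both and have no value with 1 left out. No paired analysis was possible because there was 1 group. Sequencing depth is unknown, so the absence of a region from a list does not show that it was unbound. The rRNA class gave no odds ratio without replicate 5, since neither set held such a region.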

Other observations

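The motif search at the 50 highest regions, the 8 bp words and the comparisons of X with autosomal regions were tests chosen only after the regions had been seen, as were the GC test on the 50 highest regions and the test of each replicate; those of GC content over the whole list, of short non-coding genes and of the recruitment motif were set down after the pattern was seen but before their own results.

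Regions near tRNA genes were more frequent among X regions than among autosomal ones. A tRNA gene lay within 200 bp of 65 of 310 X regions (20.97%, 95% exact interval 16.6–25.9) and 31 of 666 autosomal ones (4.65%, 3.18–6.54), an odds ratio of 5.42 (3.39–8.84, two-sided Fisher's exact test, p = 3.92e-14, adjusted p = 3.92e-13 over 10 tests). The other candidates differed in the same direction, with 1.99% on X and 0.762% on the autosomes, and X held more regions per Mb. The comparisons of X with autosomes did not adjust for either. Counted by gene, 72 of 276 X tRNA genes (26.1%) and 38 of 336 autosomal ones (11.3%) had a region nearby (odds ratio 2.76, two-sided Fisher's exact test, p = 2.64e-06, adjusted p = 6.59e-06). The highest were WBGene00022939 (X:8036685–8036757, 1222), inside the region upstream of xol-1, where 1222 is the signal of the lower summit, and WBGene00023117 (X:410391–410462, 848). snoRNA genes went the other way, near 1 X region and 49 autosomal ones (two-sided Fisher's exact test, p = 1.43e-07, adjusted p = 4.75e-07), but only 33 of the snoRNA genes are on X, and by gene the shares of 1 of 33 and 50 of 313 did not pass (p = 0.0657, adjusted p = 0.110). snRNA genes were near 1 X region and 18 autosomal ones (two-sided Fisher's exact test, adjusted p = 0.0219), but by gene the shares of 1 of 3 and 16 of 126 had the other direction and did not pass (adjusted p = 0.497), and the broad ncRNA class passed neither way (adjusted p = 0.643 by region and 0.782 by gene). The replicates shared X regions more often than autosomal ones (227 of 302 against 404 of 704, odds ratio 2.25, 1.65–3.08, two-sided Fisher's exact test, p = 5.93e-08, adjusted p = 2.97e-07).

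Of the 13 regions with the heat shock element, 6 lay in promoter windows, those of 8 bound genes. The genes and the signals of these regions were R107.5 (437), F44E5.4 and F44E5.5 (381 each, at 1 shared region), eel-1 (188), cyn-7 and bath-36 (177 each, also shared), aco-1 (128) and bag-1 (122). F44E5.4 and F44E5.5 encode Hsp70 proteins, bag-1 an Hsp70 cochaperone and cyn-7 a cyclophilin, while none of them was in the chaperone list, which was built from gene name prefixes. The element was at 0 of the 11 bound genes of that list and at 8 of 587 other bound genes, which did not pass the two-sided Fisher's exact test. The roles of these genes were looked at only after the genes were seen, so a link of the element to chaperone genes was not shown. On the autosomes the 8 bp word with the lowest p was AGACGCAG, within 100 bp of 104 of 666 summits (15.6%) against 94 of 1998 matched candidates (4.70%, two-sided Fisher's exact test, adjusted p = 7.46e-15 over 1047 words). It was 1 of 326 words that passed as more frequent. Only words found in enough of the regions were tested, which favours words more frequent there, and the adjustment covered only these. The number that passed is therefore not support in itself.

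The strongest X regions were also searched for a known sequence. The 10 bp motif GCGCAGGGAG of the recruitment elements on X, where the dosage compensation complex loads in hermaphrodites, was present with up to 1 mismatch within 100 bp of the summit at 14 of the 32 X regions among the 50 highest and at 0 of 96 matched candidates (two-sided Fisher's exact test, p = 2.71e-10). Without a mismatch it was at 4 of 32 against 0 of 96 (two-sided Fisher's exact test, p = 0.00337). It was at 0 of the 18 autosomal regions among the 50 highest. Over all X regions it was at 24 of 310 (7.74%) against 7 of 930 (odds ratio 11.04, 4.55–30.7, two-sided Fisher's exact test, p = 7.80e-10), with 21 of 183 outside promoter windows against 2 of 549, and 3 of 127 inside them against 9 of 381 (odds ratio 1). Most of these 24 were among the 32. At ranks 51 to 200 the motif was at 5 of 60 X regions against 4 of 180 (odds ratio 3.97, 0.823–20.7, two-sided Fisher's exact test, p = 0.0457). At lower ranks it was at 5 of 218 against 3 of 654 (5.08, 0.979–33.0, two-sided Fisher's exact test, p = 0.0267). Both intervals include 1, and these p-values were not adjusted. Without a mismatch the motif was at 0 of 60 X regions of ranks 51 to 200, and at 3 of 218 lower ones against 0 of 654 (two-sided Fisher's exact test, p = 0.0155). On the autosomes, with up to 1 mismatch, the motif was at 9 of 666 against 23 of 1998 (odds ratio 1.18, two-sided Fisher's exact test, p = 0.683). A search of 8 bp words that did not use the motif tested the 40 words found in enough of the strongest X regions. It put CGCAGGGA, which lies within the motif, first (13 of 32 against 0 of 96), and 31 of the 40 words passed as more frequent. Since the 40 were kept by their count in these same regions, most were bound to look more frequent, and the 31 are not support in themselves. One of the 32 lay in the promoter window of sdc-2, which directs the complex to X (X:11522110–11522459, signal 522).

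A hypothesis for the strong X regions outside promoter windows is that they are recruitment elements of dosage compensation: 43.75% of all 32 strong X regions carried the motif (26.4–62.3), as did 48.1% of the 27 outside promoter windows (28.7–68.1), and none of the matched candidates, where the test asked for a share at least 3 times higher, although 18 of the 32 did not carry it. Against an origin in 1 replicate, the lower of the shares of X among the 50 highest regions of each replicate was 64%, and against short transcribed genes, 6.25% of the 32 lay near one by the highest summit and 9.38% by any summit, the further region being the one upstream of xol-1. GC content did not account for the 50 highest, whose odds ratio of X location over matched candidates was 6.74 (3.21–14.6, two-sided Fisher's exact test, p = 3.92e-08). Over the whole list, matching raised the mean GC content of the reference from 41.3% to 48.3%, near the 48.6% of the regions, and left an odds ratio of 1.66 (1.40–1.95) against 1.62 unmatched, which argues against GC content as the whole cause; the lower bound of 1.5 set beforehand was out of reach, since the unmatched one was 1.40, so this reading was chosen after the result. The share of males, in which the complex does not load, was not given, and worms without the tag and other tagged proteins were not analysed, so the hypothesis was not tested by sex and signal at these regions that does not depend on GEI-17 stays an open, untested explanation.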
